A study of Mus musculus with 14 samples.

How the data were processed

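The data were gene-level expression values of 14 Affymetrix exon arrays hybridised with biotin-labelled total RNA of 4T1 cells, 1 array per sample. Per the labels, cells were transfected with 25 nM siRNA by lipofection, the sample labels give 48 h, and RNA was isolated with Trizol. The deposited values are log2 expression levels per transcript cluster. The log2 scale was read from their range, and RMA and Affymetrix Power Tools are named per the submitters' processing notes, while the design text in the labels names the Affymetrix Exon Array Computational Tool. Their versions, background and scaling steps and the genome build are not given in the sources used here. The design text names a human exon array, whereas the identifiers matched a mouse array platform in the probe table, and the mouse symbols of that table were used. The 8 arrays of the first experiment and the 6 arrays of the second had medians that differed by 0.89.

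Arrays were assigned to groups by their titles and source names, giving 4 siCtrl, 4 siDdx5-17, 3 siDdx5-17 with macroH2A1.1 siRNA and 3 siDdx5-17 with macroH2A1.2 siRNA. Of 23332 transcript clusters, 14996 carried 1 gene symbol, 1019 several and 7317 none. Genes were named only from clusters with 1 symbol, which covered 14860 genes, and 14941 of these clusters matched a RefSeq table by Entrez identifier, all with the same symbol. Macroh2a2 lay only on a cluster with several symbols and was not named. Where a gene had several clusters, that with the highest mean over all arrays was used. The arrays' number limits precision, with a median standard error of a log2 difference of 0.142 between siDdx5-17 and siCtrl and 0.164 between the isoform depletions.

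The groups, tests, gene lists and naming rule were chosen before the data were examined. The test was limma 3.58.1 in R 4.3.3, with a linear model of the 4 group means over all 14 arrays, empirical Bayes moderation with a trend of the spread on level, and Benjamini-Hochberg adjustment over all 23332 transcript clusters. The threshold was an adjusted p of 0.05, and every adjusted p of a gene comes from limma. The comparisons were siDdx5-17 against siCtrl, each isoform depletion against siDdx5-17, and one isoform depletion against the other. SDs are between arrays, and changes between the experiments are given relative to the median of all transcript clusters.

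The genes named were Ddx5, Ddx17, Macroh2a1 and Sod3, the 10 largest rises and the 10 largest falls per comparison among genes that passed and whose groups did not overlap, and the 4 members of each list with the largest change. Members of lists outside this rule, among them Srxn1, Cat, Atf4, Edem1, Xbp1 and Rps9, and Ifi30 were named after their values were seen. The 22 lists were redox metabolism, epithelial markers, mesenchymal markers, invasion and matrix proteolysis, G1/S, G2/M, splicing factors, DEAD-box helicases, microRNA processing, interferon-stimulated genes, integrated stress and unfolded protein response, glycolysis and hypoxia, cholesterol synthesis, TGF-beta and SMAD, Wnt and beta-catenin, inflammatory chemokines and NF-kappaB, p53 pathway, histones with PARP enzymes and macroH2A partners, ribosomal proteins, and leukocyte, endothelial and fibroblast markers. Shifts of lists were tested with limma's camera on the moderated statistics, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 88 tests. Camera with an estimated correlation and fry, whose p tests whether the genes move on balance one way, were run beside it.

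Overlaps between comparisons were set beside independent lists and divisions of the siDdx5-17 arrays. The 20 simulated unchanged data sets shared 0 calls and were not used as a reference, since unchanged groups give few calls to share. Named genes whose mean in 1 group lay below the mean lower quartile of its arrays, a rule added after the values were seen, have a bound with that quartile in place of the mean, since no background signal was used here. Replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means. Between the isoform depletions the correlations were 0.138, 0.137 and 0.17 and each array correlated best with its own number. The main test had no block, and fits with the number as a block were run beside it, also with the isoform labels swapped within each number, a test added after the result was seen.

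The tests were tried on simulated data with the real levels, 23332 transcript clusters and 5 runs. To measure recovery, each run changed 100 clusters per fold size and shifted a gene list, with errors drawn independently for each cluster. The share of false calls depends on how many clusters change. For siDdx5-17 against siCtrl with a shared spread, 37% of 1.5-fold and 68.4% of 2-fold changes were recovered with 4.9% false calls. With the separate spread of each experiment, recovery was 45.2% and 74.6% with 32.4% false calls, and a fit of the 8 arrays recovered 20.4% and 55.8% with 6.37% false calls. For the isoform comparison with separate spreads, the 14-array fit recovered 27.4% and 63.4% with 10.2% false calls and the 6-array fit 42.8% and 73.8% with 7.14%. A simulated offset of 0.897 with no other change gave 21484 to 21576 calls as deposited and 0 after quantile normalization. That offset was the same for every cluster, and quantile normalization removes such an offset by construction. The real offset varied with level, and differences of single genes between experiments were not simulated. The 0 therefore does not tell whether real calls left after that normalization are free of experiment differences.

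Alternatives numbered 18 planned and 7 added after the data were seen, among them quantile normalization, median centring, leaving out the dimmest 25% of transcript clusters, a fit of only the arrays compared, a replicate block, array weights, a 1.5-fold minimum, a threshold of 0.01, other list tests, and leaving out each array in turn. Added were list tests on only the arrays compared, list tests and overlaps after quantile normalization, normalization within each experiment, a block over only the arrays compared, and leaving out both arrays numbered 4 without and with siCtrl replicate 3. The design text calls the replicates technical. Exon-level values and read-level data were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.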

Results

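RNA from 4T1 cells, a mouse mammary carcinoma line that spreads from the mammary fat pad to distant organs, was profiled on Affymetrix exon arrays. The cells had been transfected by lipofection with 25 nM siRNA, and the labels give 48 h as the time of RNA isolation. One group of 4 arrays received a control siRNA (siCtrl), and another group of 4 arrays received siRNAs against Ddx5 and Ddx17, paralogous DEAD-box RNA helicases (siDdx5-17). A further 3 arrays received these siRNAs together with one against the macroH2A1.1 splice isoform of the histone variant macroH2A1, and 3 arrays received them with one against the macroH2A1.2 isoform. The siCtrl and siDdx5-17 arrays are called the first experiment and the 6 arrays with a macroH2A1 siRNA the second, following the separate accounts of them in the design text. The replicates are technical per that text, so p-values measure only the spread between these samples. The number of arrays limits the precision of every difference.

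Each array gave a log2 level for 23332 transcript clusters, of which 14996 carried exactly 1 gene symbol. The median level lay between 6.61 and 6.80 on the 8 arrays of the first experiment and between 7.61 and 7.67 on the 6 arrays of the second, a difference of 0.89 between the mean medians. Correlations across transcript clusters ranged from 0.950 to 0.991 among the 28 pairs of arrays within the first experiment, from 0.988 to 0.992 among the 15 pairs within the second, and from 0.916 to 0.947 among the 48 pairs between them. The root mean square deviation from the group mean was 0.459 for siCtrl replicate 3, 0.348 for siCtrl replicate 4 and 0.318 for siDdx5-17 replicate 4. It was at most 0.282 for each of the other arrays of the first experiment and at most 0.194 in the second.

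The first comparison asked what depletion of both helicases did to transcript levels. Ddx5 measured 10.80, 10.83, 10.55 and 10.98 on the siCtrl arrays and 9.44, 9.32, 9.55 and 9.16 on the siDdx5-17 arrays. Its mean fell from 10.79 ± 0.179 to 9.37 ± 0.169 (SD, n = 4 each), which is 2.69-fold lower (log2 change -1.43, SE 0.133, adjusted p = 6.4e-05). Ddx17 fell from 10.79 ± 0.255 to 9.67 ± 0.359, 2.16-fold lower (log2 change -1.11, SE 0.165, adjusted p = 0.0013). No siDdx5-17 array overlapped a siCtrl array for either gene. Macroh2a1, which encodes both macroH2A1 isoforms, measured 9.83 ± 0.129 against 10.24 ± 0.214 and missed the threshold as deposited (log2 change -0.41, adjusted p = 0.0624), and in the 8-array fit (adjusted p = 0.145). It passed without siDdx5-17 replicate 4 (adjusted p = 0.0456), after quantile normalization (-0.42, adjusted p = 0.0129), with the replicate number as a block (0.00418) and with array weights (0.00653). Sod3, which encodes the extracellular superoxide dismutase, measured 7.62 ± 0.364 against 7.16 ± 0.254 and did not pass (log2 difference 0.46, SE 0.214, adjusted p = 0.252), while it passed with the replicate number as a block (adjusted p = 0.0287) and with array weights (0.52, adjusted p = 0.0193). The array weights rested mostly on 1 siCtrl array, with 9.3 for siCtrl replicate 1 against 0.718, 0.143 and 0.224 for replicates 2 to 4. For the block, only the siCtrl and siDdx5-17 arrays numbered 4 deviated together (correlation 0.647). Passing in these 2 settings is therefore weak evidence for Macroh2a1 and Sod3. The gene-level values pool the exons of each gene and do not separate macroH2A1.1 from macroH2A1.2.

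**Figure D1:**
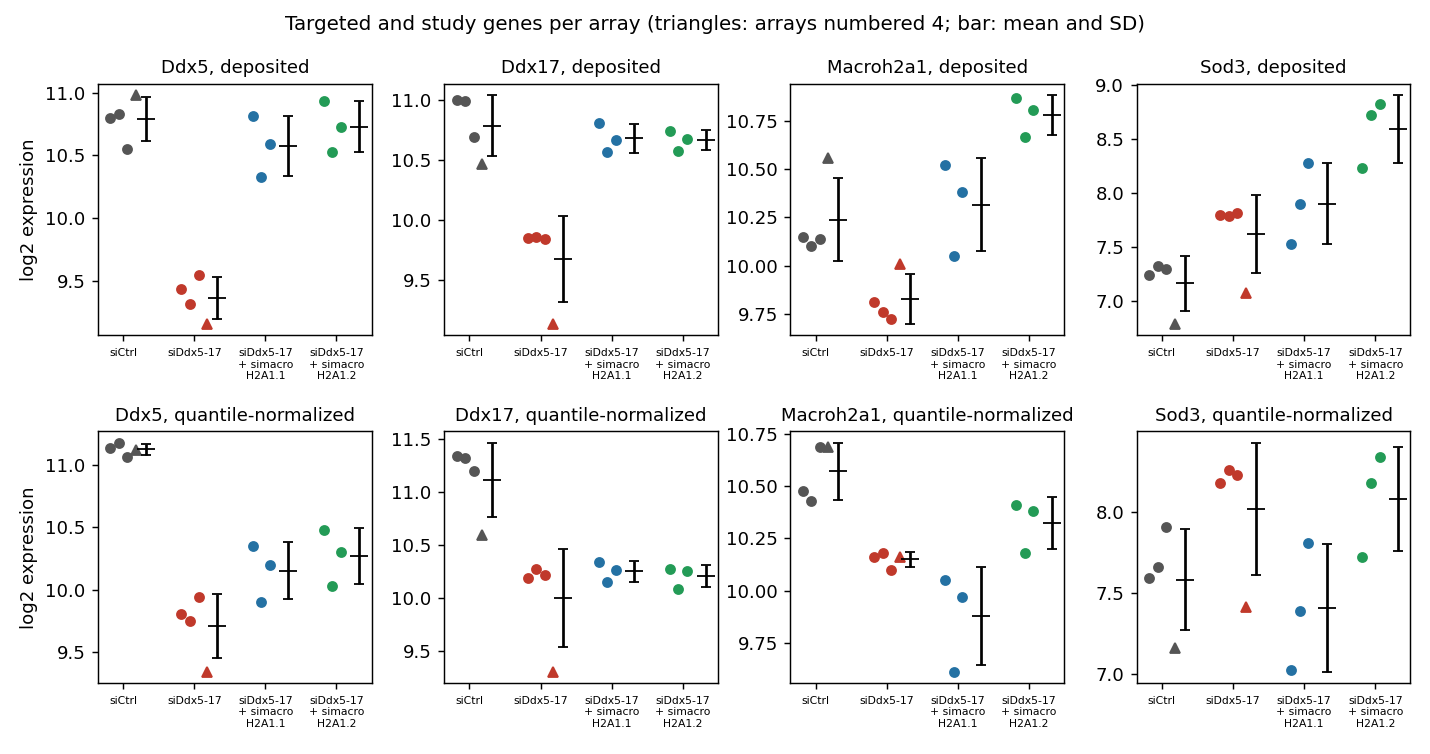
Log2 expression (vertical axes) of Ddx5, Ddx17, Macroh2a1 and Sod3 on each of the 14 arrays by siRNA group (horizontal axes), as deposited in the upper panels and after quantile normalization in the lower ones, where each point is an array, triangles are the arrays numbered 4, and bars give the group mean and SD. Ddx5 averaged 10.79 in siCtrl and 9.37 in siDdx5-17 as deposited, and the groups with a macroH2A1 siRNA averaged 10.58 and 10.73 as deposited but 10.15 and 10.27 after quantile normalization, against 11.13 in siCtrl.

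The largest rise was that of S100a7a, a small calcium-binding protein of the psoriasin family, from 6.54 ± 0.911 to 9.59 ± 0.132 (8.27-fold, log2 change 3.05, SE 0.343, adjusted p = 0.000214). A3galt2 rose 6.16-fold (adjusted p = 2.61e-07), H2-DMa, a chaperone of antigen loading onto class II histocompatibility molecules, rose at least 5.20-fold (adjusted p = 0.000334), and Tex29 rose at least 3.89-fold (adjusted p = 7.99e-06), since both lay below the lower quartile of levels in siCtrl and that quartile was set in place of their means. Scd4, a stearoyl-CoA desaturase, rose 3.45-fold, Bhlha15, a transcription factor of secretory cells, 3.42-fold, Car15, a carbonic anhydrase, 3.41-fold, the actin-binding Avil 3.13-fold, and the small GTPase Rhof 2.91-fold. The largest fall was that of Krcc1, which ended 4.19-fold lower (log2 change -2.07, SE 0.213, adjusted p = 0.000126). Nt5dc1 fell 3.39-fold, Ccdc122, below that quartile in siDdx5-17, at least 1.86-fold, the O-mannosyltransferase Tmtc4 3.25-fold and Micu2, a regulator of the mitochondrial calcium uniporter, 3.21-fold. Nipsnap2 was 3.17-fold lower, the polymerase III transcription factor subunit Gtf3c1 2.83-fold, Cnp 2.82-fold, the volume-regulated anion channel subunit Lrrc8c 2.80-fold, and the phosphate transporter Slc20a2 2.75-fold lower. These 20 genes, including the interferon-induced Ifit1 at 3.14-fold, were the 10 largest rises and the 10 largest falls as measured under the naming rule, and each also passed in a fit of the 8 arrays of the first experiment alone.

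**Figure D2:**
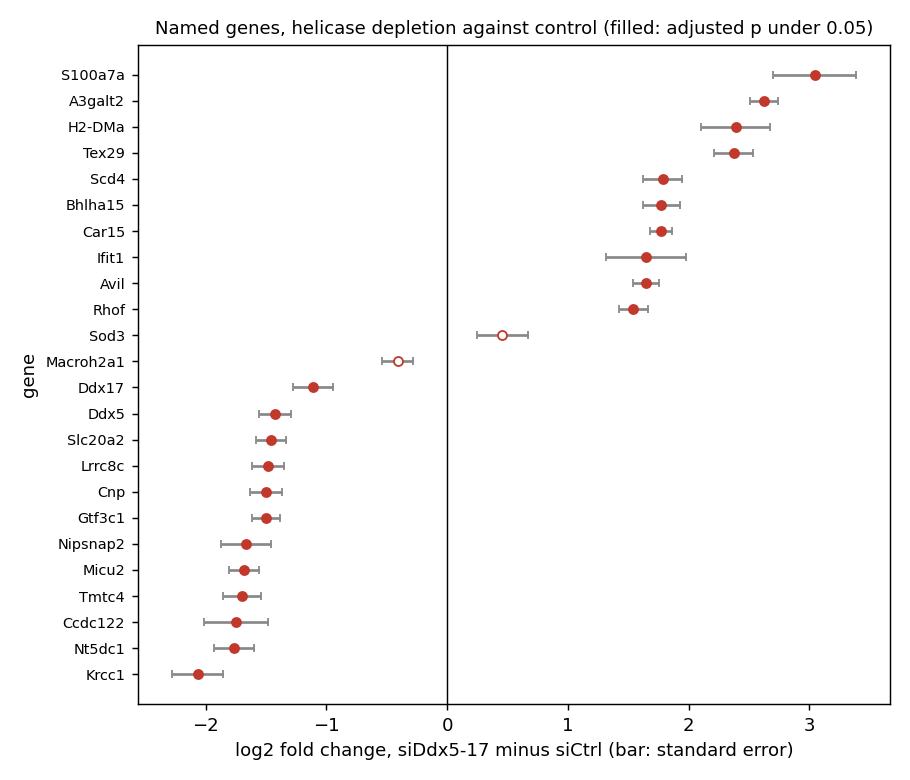
Log2 change in siDdx5-17 against siCtrl (horizontal axis, 4 arrays each, bars are the standard error) for the named genes (vertical axis), with filled points where the adjusted p was under 0.05. S100a7a had the largest rise at 3.05 and Krcc1 the largest fall at -2.07, while Macroh2a1 at -0.41 and Sod3 at 0.46 did not pass.

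Several genes of the integrated stress and unfolded protein response rose in siDdx5-17. Of 26 measured, 7 rose, 2 fell and 17 did not pass, and 9 rose and 2 fell when adjusted over the list alone. The pseudokinase Trib3 rose 2.71-fold (log2 change 1.44, SE 0.144, adjusted p = 0.000104), the transcription factor Ddit3 (CHOP) 2.61-fold (adjusted p = 0.00379), the glutathione-degrading Chac1 2.41-fold (adjusted p = 5.56e-05) and Atf3 2.27-fold (adjusted p = 0.00591). Atf4, a central activator of the response, rose by 0.55, while Edem1 fell by 0.71 and Xbp1 by 0.42, the latter both acting in the endoplasmic reticulum branch. The list shifted upward against the other genes (median 0.18, camera adjusted p = 7.3e-05), with adjusted p = 0.991 with an estimated correlation and 0.00448 with fry. The shift passed without any single array, at adjusted p of at most 0.00335.

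The p53 pathway list, with 24 measured genes, had 3 that rose and none that fell, the same counts as when adjusted over the list alone. Gadd45a rose 2.22-fold (adjusted p = 0.00108) and the cell-cycle inhibitor Cdkn1a 1.71-fold (adjusted p = 0.00684). The list shifted upward (median 0.14, adjusted p = 0.0309), with adjusted p = 0.991 with an estimated correlation, and the shift was lost without siCtrl replicate 2 (adjusted p = 0.0629) or siCtrl replicate 3 (0.142). Of 26 interferon-stimulated genes, 6 rose and 1 fell, and 6 rose and 2 fell when adjusted over the list alone. Ifit1 rose 3.14-fold (adjusted p = 0.00764), the antiviral Oasl1 2.20-fold (adjusted p = 0.00271), the chemokine Cxcl10 1.84-fold (adjusted p = 0.00359) and Ifit2 1.61-fold (adjusted p = 0.00799). That list did not shift as a whole (adjusted p = 0.426), and its median was -0.01 against a mean of 0.14. Of 49 redox genes, 4 rose and none fell, also when adjusted over the list alone. The thioredoxin inhibitor Txnip rose 2.62-fold (adjusted p = 6.54e-05), Srxn1 by 0.57 and Cat by 0.43. The cystine transporter Slc7a11 rose 2.30-fold (adjusted p = 0.0318) but lost the call without siCtrl replicate 3 (0.0545) or without siDdx5-17 replicate 1 (0.0901), 2 (0.0803) or 3 (0.0944). The redox list was prompted by what is known of the study and is not independent evidence, and it did not shift (adjusted p = 0.462).

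Of 26 measured G1/S genes, 6 fell, none rose and 20 did not pass, the same counts as when adjusted over the list alone. Thymidylate synthase Tyms fell by 0.74 (adjusted p = 0.00156), the polymerase epsilon subunit Pole by 0.59 (adjusted p = 0.00538), Uhrf1 by 0.56 (adjusted p = 0.00181) and the replicative helicase subunit Mcm7 by 0.54 (adjusted p = 0.004). Changes were positive for 12 members and negative for 14. The list shifted downward (median -0.02, mean -0.11, adjusted p = 0.0309), with adjusted p = 0.991 with an estimated correlation and 0.301 with fry. The shift was lost without siCtrl replicate 4 (adjusted p = 0.314) or siDdx5-17 replicate 1 (0.0529), 2 (0.105) or 3 (0.0974). Of 27 G2/M genes, 2 rose and 3 fell, or 2 and 4 when adjusted over the list alone, and the list did not shift (adjusted p = 0.619). The cyclin Ccnb2 fell by 0.49 (adjusted p = 0.00673).

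Of 16 measured genes of microRNA processing, 5 fell, 1 rose and 10 did not pass, the same counts as when adjusted over the list alone. Tnrc6c, a scaffold of microRNA silencing, was 2.02-fold lower (adjusted p = 0.00668), the Argonaute Ago1 1.74-fold (adjusted p = 0.00768), and the terminal uridylyltransferase Tut7 1.47-fold lower (adjusted p = 0.0119). Drosha, the nuclear nuclease whose complex contains Ddx5 and Ddx17, fell by 0.68 (adjusted p = 0.0059). The shift of the list (median -0.10, adjusted p = 0.0309) had adjusted p = 0.991 with an estimated correlation and 0.0205 with fry. It was lost without siCtrl replicate 2 (0.0738), siCtrl replicate 4 (0.0909) or siDdx5-17 replicate 2 (0.0567). No gene of this list passed in the 8-array fit, where Drosha had adjusted p = 0.0524. Of 37 splicing factors, 5 rose and 1 fell, or 7 and 1 when adjusted over the list alone and 1 and 1 in the 8-array fit, and the list did not shift (adjusted p = 0.109). Mbnl2 rose by 0.57 (adjusted p = 0.00182). Of 24 other DEAD-box and related helicases, 1 rose and 2 fell, also when adjusted over the list alone, with the messenger RNA export helicase Ddx39b 1.69-fold lower (adjusted p = 0.00152) and no shift of the list (adjusted p = 0.806). Among 28 genes of histones, PARP enzymes and macroH2A partners, 1 rose and 3 fell, or 2 and 3 when adjusted over the list alone. The DNA methyltransferase Dnmt3a fell by 0.57 (adjusted p = 0.00292), and the list (adjusted p = 0.749) had a median of 0.02, a mean of -0.01 and a downward test.

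Of 17 fibroblast markers, 4 fell and none rose, also when adjusted over the list alone. The receptor Pdgfrb was 2.15-fold lower (log2 change -1.11, SE 0.102, adjusted p = 6.24e-05), and the collagen VI chain Col6a1 was also 2.15-fold lower (-1.10, SE 0.215, adjusted p = 0.00633). The list shifted downward (median -0.09, adjusted p = 0.0121), with adjusted p = 0.991 with an estimated correlation, and the shift was lost without siCtrl replicate 3 (0.213) or siDdx5-17 replicate 4 (0.106). Of 27 TGF-beta and SMAD genes, 6 fell and none rose, also when adjusted over the list alone, while 1 fell in the 8-array fit, with the cytokine Tgfb1 itself 1.92-fold lower (adjusted p = 0.00175). That list shifted downward (median -0.08, adjusted p = 0.0382), with adjusted p = 0.991 with an estimated correlation and 0.0483 with fry. The TGF-beta shift was lost without siCtrl replicate 2 (0.0628), 3 (0.0929) or 4 (0.131) and without siDdx5-17 replicate 1 (0.0529), 2 (0.0524) or 3 (0.0923), so only the leave-outs of siCtrl replicate 1 (0.0389) and siDdx5-17 replicate 4 (0.0244) kept it.

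Of 39 invasion and matrix proteolysis genes, 2 rose and 5 fell, or 2 and 7 when adjusted over the list alone. The membrane-anchored matrix metalloproteinase Mmp14 was 2.05-fold lower (adjusted p = 0.00343), the collagenase Mmp13 fell by 0.57 (adjusted p = 0.0113) and the fibronectin receptor subunit Itga5 by 0.56 (adjusted p = 0.00766), and the list did not shift (adjusted p = 0.378). Of 23 mesenchymal markers, 1 fell, or none when adjusted over the list alone, and the list did not shift (adjusted p = 0.282). That gene was Zeb1, a repressor of epithelial genes, at a log2 change of -0.39 (adjusted p = 0.0458) between levels near the lower quartile. Zeb1 lost its call without siCtrl replicate 1 (0.0908), 3 (0.0644) or 4 (0.064) and without each of siDdx5-17 replicates 1 to 4 (0.0693, 0.0738, 0.12 and 0.108). Of 21 epithelial markers, 1 rose, also when adjusted over the list alone, with no shift of the list (adjusted p = 0.828). That gene was the mucin Muc1, with a log2 change of 0.68 (adjusted p = 0.0156), which did not pass without siCtrl replicate 1 (0.0517). The epithelial markers were higher on the arrays numbered 4 than on arrays 1 to 3 of the same group, by a median of 0.87 in siCtrl and 0.70 in siDdx5-17.

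Of 20 Wnt and beta-catenin genes, 1 rose and 1 fell, or 2 and 2 when adjusted over the list alone (list adjusted p = 0.806). The matricellular Ccn4 was 1.88-fold lower (adjusted p = 0.00476) and Jun rose by 0.57 (adjusted p = 0.0163). Of 27 inflammatory and NF-kappaB genes, 2 fell, also when adjusted over the list alone, and the list did not shift (adjusted p = 0.123). Those genes were Il33 (log2 change -0.79, adjusted p = 0.0286) and Nfkbia (-0.51, adjusted p = 0.0164). Nfkbia did not pass without siDdx5-17 replicate 2 (0.0524) or 3 (0.0531), and Il33 did not pass without siCtrl replicate 1 (0.0877) or 2 (0.0758) or without siDdx5-17 replicates 1 to 4 (0.0559, 0.0667, 0.055 and 0.0709). Of 26 glycolysis and hypoxia genes, 4 rose and 1 fell, or 6 and 2 when adjusted over the list alone, with a list adjusted p of 0.12. The stress-responsive Ndrg1 rose 2.30-fold (adjusted p = 0.00214) and the mitophagy receptor Bnip3 1.53-fold (adjusted p = 0.00622), while the prolyl hydroxylase Egln3 was 2.37-fold lower (adjusted p = 0.00754). Of 18 cholesterol synthesis genes, 2 rose and 3 fell, or 3 and 4 when adjusted over the list alone (list adjusted p = 0.462). Hsd17b7 rose by 0.43 (adjusted p = 0.000874) and Mvk fell by 0.54 (adjusted p = 0.00777).

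Of the 40 ribosomal protein genes listed, 10 were measured, and all 10 had a negative change with a median of -0.31. Only Rps9 passed (log2 change -0.31, adjusted p = 0.017), also when adjusted over the list alone, and it did not pass without siDdx5-17 replicate 3 (0.0588). The list did not shift (adjusted p = 0.109). None of 19 leukocyte markers passed, also when adjusted over the list alone. Their list adjusted p was 0.897, with a median of -0.01, a mean of 0.01 and a downward test. Of 15 endothelial markers, 1 rose, or 2 when adjusted over the list alone, and the list did not shift (adjusted p = 0.806). That gene was the adhesion molecule Esam (0.48, adjusted p = 0.0188), which did not pass without siCtrl replicate 1 (0.0602), siCtrl replicate 2 (0.0532) or siDdx5-17 replicate 4 (0.0524).

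Between siDdx5-17 and siCtrl, 2077 transcript clusters passed an adjusted p of 0.05 in limma, 957 higher and 1120 lower, and 224 of these changed at least 2-fold, 136 upward and 88 downward. The balance turned on single arrays, with 979 higher and 1776 lower without siCtrl replicate 3, and 1520 higher and 1191 lower without siCtrl replicate 4. The groups did not overlap in 2707 transcript clusters, or 11.6%, where chance gives 2.86%. The spread was larger in the first experiment (median residual SD 0.231) than in the second (0.119), and the fit pools both. In data simulated with these separate spreads the pooled fit had 32.4% false calls against 6.37% for the 8 arrays alone. Only 100 transcript clusters per fold size and a gene list changed there, so these are not the false shares of the real calls. On the real data the fit of the 8 arrays alone called 721 transcript clusters (308 higher, 413 lower), 716 of them shared with the pooled fit. Ddx5 (adjusted p = 0.00293) and Ddx17 (0.0251) passed in that 8-array fit. Of the list members, Mmp13, Itga5, Ccnb2, Tnrc6c, Ago1, Tut7, Ifit2, Atf3, Mvk and Jun did not, with 8-array adjusted p-values of 0.0619, 0.0679, 0.065, 0.0563, 0.058, 0.095, 0.0698, 0.0511, 0.0533 and 0.0794. In that fit 5 stress response, 3 redox, 3 interferon, 2 p53, 2 glycolysis and hypoxia, 1 epithelial, 1 cholesterol and 1 splicing gene rose. Lower in it were 5 G1/S, 2 fibroblast and 2 invasion genes, and 1 gene each of the splicing, helicase, TGF-beta, Wnt, inflammatory, histone, glycolysis and stress lists, while the other lists had 0. Also outside the threshold there were Slc7a11 (0.152), Zeb1 (0.167), Nfkbia (0.0736), Esam (0.0823), Xbp1 (0.079) and Rps9 (0.112).

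The comparisons with added isoform depletion asked what depletion of macroH2A1.1 or macroH2A1.2 added to helicase depletion. All arrays with a macroH2A1 siRNA belong to the second experiment and all siDdx5-17 arrays to the first, so batch and group cannot be told apart in either comparison. The median log2 difference over all transcript clusters was 0.84 for macroH2A1.1 and 0.85 for macroH2A1.2, and changes across the experiments are given relative to it. This difference varied with level. In 10 groups of clusters ranked by mean, its median over both isoform groups ran from 0.671 in the highest group to 1.02 in a low one. Values relative to 1 median, also those of lists, can therefore carry part of that dependence on level, which was not tested. Hmgn5, a nucleosome-binding protein, was at least 2.56 above the shift in both groups, taking the lower quartile of levels for siDdx5-17, where it lay below that. It stood at 8.61 ± 0.219 with macroH2A1.1 depletion and 8.62 ± 0.192 with macroH2A1.2 depletion (n = 3 each) against 3.84 ± 0.134 in siDdx5-17 (n = 4), with adjusted p-values of 3.59e-10 and 3.46e-10. The adherens junction protein Cdh1 was 2.88 above the shift with macroH2A1.1 depletion, where it stood at 11.97 ± 0.19 against 8.25 ± 0.914, and it measured 12.03, 11.90 and 11.66 on the arrays with macroH2A1.2 depletion. The epithelial trafficking GTPase Rab25 was 3.22 and 3.21 above it, and the centromere protein Cenpv 3.34 and 3.30. The mitochondrial Uqcc2 (3.50 and 3.56) and Ndufa2 (2.97 and 2.96) were also higher. Other high genes were Washc3 (3.41 and 3.41), the testis histone H2bc1 (at least 2.76 and 2.24, by the same bound), Larp7 (2.87 and 3.01) and, with macroH2A1.2 depletion, the growth factor Bmp7 (2.89). Mal2 was 3.85 and 3.76 above the shift, with an SD of 1.66 in siDdx5-17.

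Among the largest falls, Pdgfra, a platelet-derived growth factor receptor, gave -3.48 relative to the shift with macroH2A1.1 depletion and -3.63 with macroH2A1.2 depletion. In the same order, the collagen chain Col1a1 gave -3.07 and -3.04, the vessel growth factor Angpt1 -3.74 and -2.91, while the receptor Calcrl and the zinc transporter Slc39a1 ended below the lower quartile, which gives bounds of -1.96 and -1.97 for Calcrl and -2.39 and -2.41 for Slc39a1. Values for the mitochondrial cristae protein Micos10 were -3.21 and -3.28, for Cstf2t -2.76 and -2.71, for biliverdin reductase Blvra -2.46 and -2.49 and for AY036118 -2.49 and -2.69. Pdcl gave -2.39 with macroH2A1.1 depletion and Otud6b -2.34 with macroH2A1.2 depletion. Each of these genes passed in the same direction after quantile normalization of all 14 arrays.

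**Figure D3:**
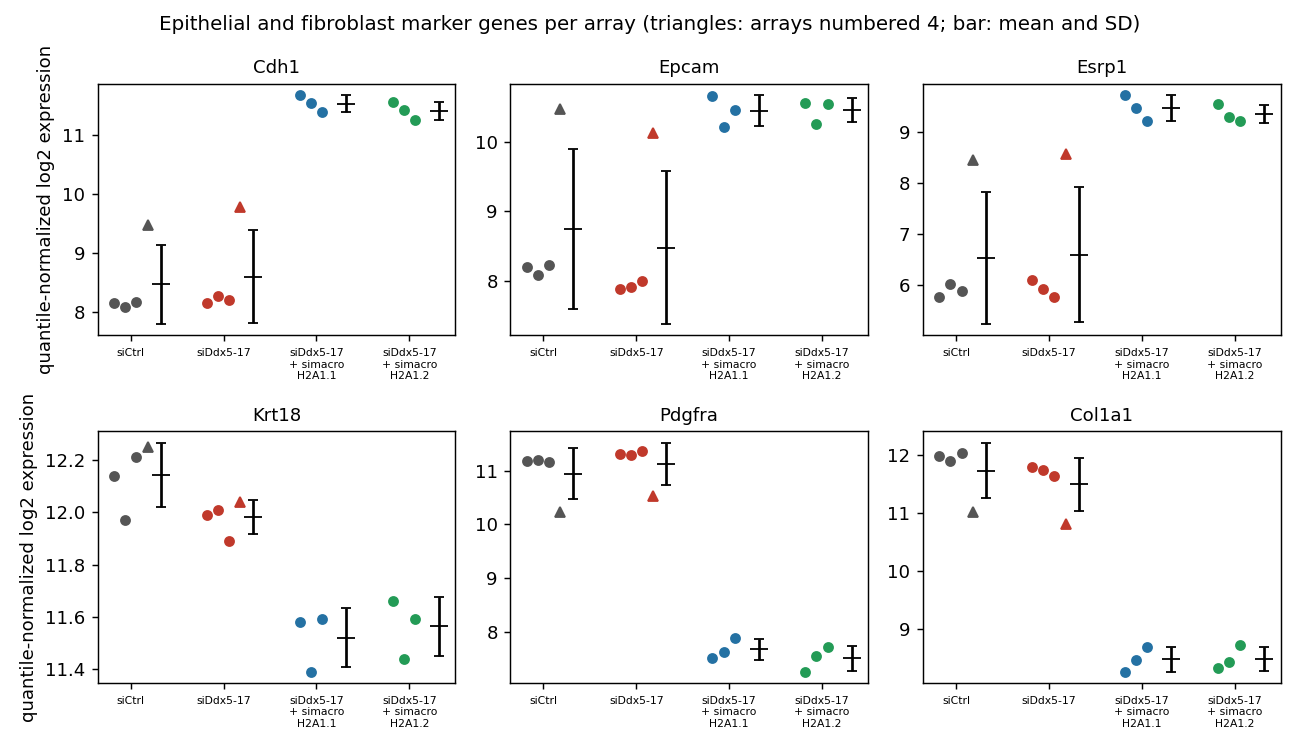
Quantile-normalized log2 expression (vertical axes) of Cdh1, Epcam, Esrp1, Krt18, Pdgfra and Col1a1 on each of the 14 arrays by siRNA group (horizontal axes), where each point is an array, triangles are the arrays numbered 4, and bars give the group mean and SD. Over the 6 arrays of the second experiment against arrays 1 to 3 of both groups of the first, Cdh1 differed by 3.30, Epcam by 2.40 and Esrp1 by 3.48, Pdgfra by -3.65, Col1a1 by -3.36 and Krt18 by -0.49.

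Relative to the shift, Ddx5 was 0.37 higher with macroH2A1.1 depletion and 0.51 higher with macroH2A1.2 depletion than in siDdx5-17, and its quantile-normalized differences of 0.44 (adjusted p = 0.0234) and 0.56 (adjusted p = 0.00655) passed. Ddx17 was 0.17 and 0.14 above the shift, with quantile-normalized differences of 0.26 (adjusted p = 0.365) and 0.21 (adjusted p = 0.463). Macroh2a1 was 0.49 higher with macroH2A1.1 depletion as deposited (adjusted p = 0.00477), which is -0.35 relative to the shift, and it turned to -0.27 after quantile normalization (adjusted p = 0.052) and to -0.37 after median centring (adjusted p = 0.0339). With macroH2A1.2 depletion it lay 0.10 above the shift (quantile-normalized 0.18, adjusted p = 0.189). Sod3 gave -0.56 relative to the shift with macroH2A1.1 depletion (quantile-normalized -0.61, adjusted p = 0.0582) and 0.11 with macroH2A1.2 depletion (0.06, adjusted p = 0.863).

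Among the lists, DEAD-box helicases lay below the other genes in both comparisons, with medians relative to the shift of -0.58 each and camera adjusted p-values of 0.000164 and 0.000251. Splicing factors did so with medians of -0.45 (adjusted p = 0.0192) and -0.43 (adjusted p = 0.0309), and glycolysis and hypoxia genes with macroH2A1.1 depletion (-0.38, adjusted p = 0.0309). Endothelial markers lay above the other genes by 0.13 (adjusted p = 0.0392) and 0.09 (adjusted p = 0.0307), calls that ended after quantile normalization (adjusted p = 0.839 and 0.763). All these had adjusted p = 0.991 with an estimated correlation. With the replicate number as a block none of these calls remained, with adjusted p-values of 0.0964 and 0.204 for DEAD-box helicases, 0.229 and 0.312 for splicing factors, 0.0684 for glycolysis and 0.43 and 0.35 for endothelial markers. With that block epithelial markers lay above the other genes (adjusted p = 1.96e-10 and 2.22e-10), as did TGF-beta genes with macroH2A1.1 depletion (0.0404) and G2/M genes with macroH2A1.2 depletion (0.0404). As deposited, these lists had adjusted p = 0.997 with an estimated correlation. Number 4 occurs only in the first experiment, so the block takes the level shared by the arrays numbered 4 out of these comparisons. Epithelial markers were higher on those arrays than on arrays 1 to 3 of the same group. Glycolysis was lost without replicate 2 of the macroH2A1.1 group (adjusted p = 0.0721), splicing factors for macroH2A1.2 without siDdx5-17 replicate 4 (0.0755), and endothelial markers without siDdx5-17 replicate 4 (0.103 and 0.0574) and, for macroH2A1.1, without siDdx5-17 replicate 3 (0.0534) or its own replicate 2 (0.0693). Of 21 epithelial markers, 19 were higher and 1 lower with macroH2A1.1 depletion and 20 and 1 with macroH2A1.2 depletion, also when adjusted over the list alone, counts that include the shift. Their medians lay 0.99 and 0.93 above the shift, and the list passed after quantile normalization (adjusted p = 0.0435 and 0.0401) but not as deposited (0.619 and 0.619, or 0.997 each with an estimated correlation). Fibroblast markers had medians of -0.19 and -0.22 relative to the shift and did not pass (adjusted p = 0.329 and 0.282). The other lists did not pass as deposited in either comparison. After quantile normalization 5 lists lay lower with macroH2A1.1 depletion, with G1/S (adjusted p = 0.0454) and cholesterol synthesis (0.0477) beside splicing factors (2.45e-07), DEAD-box helicases (0.000234) and glycolysis (0.0425). G1/S and cholesterol synthesis had adjusted p = 0.991 with an estimated correlation. For macroH2A1.2 splicing factors (2.45e-07) and DEAD-box helicases (0.000238) lay lower after that normalization. For the invasion, microRNA and histone lists the test pointed up while the median lay below the shift, and for the p53 list the test pointed down while the median lay above it. With macroH2A1.2 depletion the G2/M and interferon lists also had a median below the shift and an upward test.

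As deposited, 18499 transcript clusters passed with macroH2A1.1 depletion, 17629 higher and 870 lower, and 18599 with macroH2A1.2 depletion, 17835 higher and 764 lower. After quantile normalization the counts were 11351 (5534 higher, 5817 lower) and 11027 (5380 higher, 5647 lower), so the share higher moved from 95.3% and 95.9% to 48.8% in both. The groups did not overlap in 18672 and 18674 transcript clusters, 80% where chance gives 5.71%. Of the calls as deposited, 17816 were shared in the same direction and 1 in opposite directions, where independent lists would share 13500 and 1242. With the siDdx5-17 arrays split between the comparisons, 15947 to 16092 were shared in the same direction. Both comparisons set arrays of the second experiment against arrays of the first and carry the same offset, which the split does not remove. These counts therefore cannot tell a shared effect of the isoform depletions from the difference between the experiments.

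Against the helicase comparison, 722 calls of macroH2A1.1 depletion went the same way and 1036 the opposite way, where independent lists give 764.8 and 881.9. For macroH2A1.2 depletion these were 741 and 1024, against 768.2 and 887.5. Both comparisons use the siDdx5-17 arrays with opposite sign. With these arrays split over 6 divisions, 414 to 559 and 412 to 574 calls were opposite, and 252 to 447 and 252 to 454 went the same way. After quantile normalization 1087 calls were opposite for each isoform, where independent lists give 691.1 and 671.4, and 740 and 716 went the same way, against 692.5 and 672.7. With the arrays split these were 516 to 672 and 515 to 657 opposite, and 329 to 551 and 322 to 526 the same way.

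The last comparison set macroH2A1.1 depletion directly against macroH2A1.2 depletion, with siRNAs against the helicases in both and all 6 arrays in the second experiment. Macroh2a1 measured 10.32 ± 0.242 against 10.78 ± 0.104 (SD, n = 3 each), a difference of -0.47 that did not pass (SE 0.144, adjusted p = 1). Sod3 measured 7.90 ± 0.371 against 8.59 ± 0.316 (-0.69, SE 0.247, adjusted p = 1), and Ddx5 and Ddx17 differed by -0.15 and 0.01. No gene passed in limma, where 556 had an unadjusted p under 0.05 against 1167 expected by chance, and the lowest adjusted p was 0.294. That fit pools the larger spread of the first experiment (median residual SD 0.231) with that of the second (0.119). In data simulated with separate spreads it recovered 27.4% of 1.5-fold changes, against 42.8% for the 6 arrays alone. The count below chance is therefore no evidence that the isoform depletions do not differ. A fit of the 6 arrays alone also called 0, with 1616 unadjusted and a lowest adjusted p of 0.256, and with the replicate number as a block over all 14 arrays there were 0 calls, with 1061 unadjusted. The block over the 6 arrays alone called 2 genes, with 3481 unadjusted. With the isoform labels swapped within number 1, 2 or 3 that fit called 0 each time, with 957, 935 and 777 unadjusted. Slc7a11, the cystine transporter, was higher with macroH2A1.1 depletion at 12.11 ± 0.161 against 11.04 ± 0.158 (difference 1.06, blocked adjusted p = 0.00887), and Ifi30, a lysosomal thiol reductase, was lower at 11.03 ± 0.201 against 11.78 ± 0.231 (difference -0.75, blocked adjusted p = 0.0451). The groups did not overlap in 2795 transcript clusters, 12% where chance gives 10%.

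Cell-cycle genes lay slightly lower with macroH2A1.1 depletion. Of 26 G1/S genes, 25 had a negative difference, with a median of -0.11 (camera adjusted p = 0.00224) and Slbp (-0.95), Ccne1 (-0.38) and E2f2 (-0.26) the largest. Of 27 G2/M genes, 25 were negative, with a median of -0.08 (adjusted p = 0.0108) and the mitotic kinesin Kif2c at -0.37 and the centromere histone Cenpa at -0.24. Of 26 glycolysis and hypoxia genes, 22 were negative (adjusted p = 0.0108), among them Pdk1 (-0.36), Bnip3 (-0.34) and the glucose transporter Slc2a1 (-0.32). The 3 lists had adjusted p = 0.991 with an estimated correlation, and fry, which tests whether the genes move on balance one way without comparing them with other genes, gave adjusted p-values of 0.489, 0.554 and 0.215. No member of any of these lists passed over all genes tested or when adjusted over the list alone. The G2/M call was lost without replicate 2 of the macroH2A1.1 group (adjusted p = 0.12), and the glycolysis call was lost without that array (0.265), without replicate 3 of the macroH2A1.2 group (0.223) and in the 6-array fit (0.135).

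**Figure D4:**
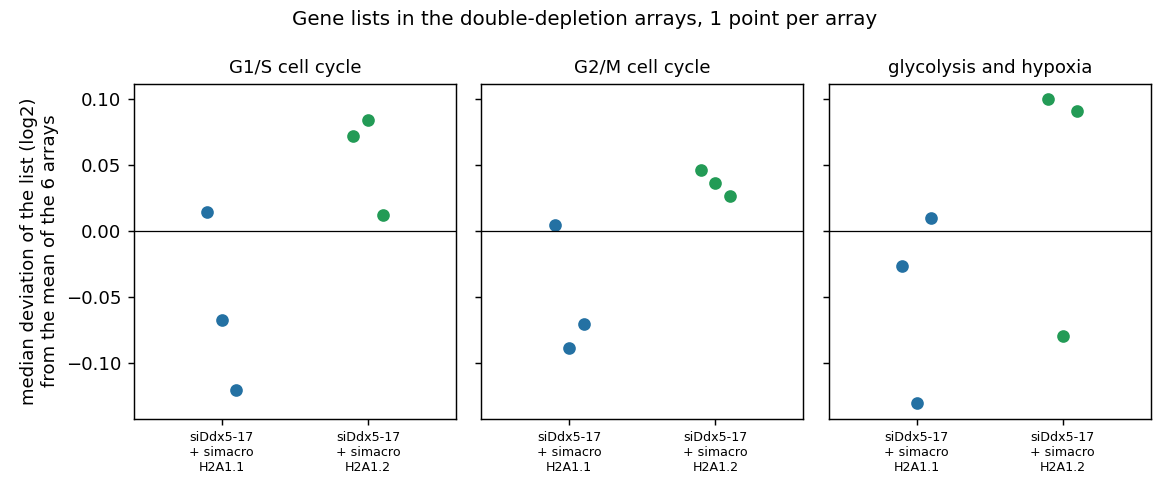
Median deviation of each list from its mean over the 6 arrays (vertical axis, log2) for the G1/S, G2/M and glycolysis and hypoxia lists (panels) on each array with a macroH2A1 siRNA (horizontal axis, 3 arrays per isoform, 1 point per array). For G1/S genes the medians were 0.01, -0.07 and -0.12 with macroH2A1.1 depletion and 0.07, 0.08 and 0.01 with macroH2A1.2 depletion.

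Of the redox list, 0 genes passed over all genes tested and 1 was lower when adjusted over the list alone. Slc7a11 had its largest difference (1.06) and passed only in the blocked fit of the 6 arrays. Txnip measured 9.30 ± 0.132 against 10.07 ± 0.186 (-0.77, SE 0.151, adjusted p = 0.882), and was the gene that passed when adjusted over the list alone. Hmox1, the heme oxygenase, measured 10.69 ± 0.31 against 9.66 ± 0.426 (1.03, adjusted p = 1). No list other than the 3 cell-cycle and glycolysis lists shifted in the main test. With the replicate number as a block over all 14 arrays 4 lists lay lower, these 3 (G1/S 3.1e-08, G2/M 3.52e-05, glycolysis 0.0308) and DEAD-box helicases (0.0396). DEAD-box helicases had adjusted p = 0.402 without the block and adjusted p = 0.997 with an estimated correlation. The interferon-stimulated genes came closest (adjusted p = 0.0921, upward), with Oasl1 at 0.65 and Rsad2 at 0.55, and passed without the dimmest 25% of transcript clusters (0.026). The stress gene Atf3 differed by 0.59, and in the p53 list Gadd45a differed by 0.60 and Cdkn1a by -0.57, each with adjusted p = 1. Epithelial markers (adjusted p = 0.952), fibroblast markers (0.705), leukocyte markers (0.402) and endothelial markers (0.406) did not shift. The mesenchymal, invasion, Wnt, fibroblast and leukocyte lists had a median below 0 and an upward test.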

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

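All tests of the epithelial marker pattern and of other divisions of the arrays were chosen after the result was seen. In groups of 4 arrays, 33 of 224 sets of values held an array whose gap to its nearest neighbour, divided by the range, passed Dixon's critical value of 0.829, and chance alone gives about 1 in 20. Of these arrays, siDdx5-17 replicate 4 accounted for 21, siCtrl replicate 4 for 6 and siCtrl replicate 3 for 3. In siCtrl, replicate 4 stood apart for Macroh2a1 (ratio 0.908), Sod3 (0.844), Col1a1 (0.838), Ddx39b (0.939), Gadd45b (0.894) and Daxx (0.845), replicate 3 for Micu2 (0.837), Chac1 (0.847) and Cd3e (0.883), and replicate 1 for Avil (0.958). In siDdx5-17, replicate 4 was lowest for Ddx17 (0.975), Sod3 (0.953), Nt5dc1 (0.946), Slc7a11 (0.901), Xdh (0.853), Fn1 (0.922), Egln3 (0.969), Ndrg1 (0.87), Pdk1 (0.862), Ccn4 (0.872) and Csf1 (0.876). It was highest for H2-DMa (0.859), Hmox1 (0.888), Krt19 (0.873), Ckap2 (0.852), Ddx52 (0.894), Ddx27 (0.893), Gadd45b (0.937), Plk2 (0.838), Rplp0 (0.908) and Cd68 (0.883). Replicate 3 stood apart for Lif (0.944) and replicate 2 for the array median (0.897).

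The epithelial markers had a higher median, and Pdgfra and Col1a1 were lower, in the 6 arrays of the second experiment and, by less, in both arrays numbered 4. Cdh1 measured 7.71 on siCtrl 1 to 3, 9.38 on siCtrl 4, 7.79 on siDdx5-17 1 to 3, 9.62 on siDdx5-17 4 and 11.92 in the second experiment, and Pdgfra 10.78, 10.10, 10.95, 10.39 and 8.11. Pdgfra and Col1a1 were named as largest falls. Against arrays 1 to 3 after quantile normalization, the second experiment had the epithelial Krt18 lower (-0.49) and the mesenchymal Vim nearly unchanged (0.06). The 17 fibroblast markers had a median of -0.318, for which no random lists were drawn. A different scale of whole arrays between the experiments is argued against, since the median difference of the 21 epithelial markers was 1.02 after quantile normalization, outside the middle 95% of 2000 random lists of like level (-0.33 to 0.277). The same holds for the scale of the arrays numbered 4, where the quantile-normalized medians above arrays 1 to 3 were 0.638 and 0.549 against at most 0.186 and 0.157 in the middle 95% of random lists. Quantile normalization does not remove differences of single genes that separate processing may leave, so those are not excluded. The random lists drew genes independently, and their range may be too narrow for markers that vary together. For the second experiment an added macroH2A1 depletion cannot be told apart from the experiment, since 0 arrays of the first had it, and per the labels those numbered 4 had none. A share of cells in the state of the second experiment could account for the arrays numbered 4 but stays open. The median positions between both states were 0.05 and 0.102 for 297 transcript clusters higher in the second experiment. They were 0.215 and 0.216 for 151 lower ones, and 67.3% to 81.1% of these sets were shifted towards the second experiment. The clusters were chosen by their difference from arrays 1 to 3, which also define the first state. Noise in arrays 1 to 3 can therefore place other arrays towards the second experiment, and no reference share was computed.

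For siDdx5-17 against siCtrl, 1 of 35 divisions of the arrays, the real one, reached 2077 calls and the highest other gave 764. That other division joined siCtrl replicate 3 to siDdx5-17 replicates 1 to 3. The divisions treat the arrays as exchangeable, while the siCtrl and siDdx5-17 arrays numbered 4 deviated together (correlation 0.647). The replicates are also technical, so these divisions cannot exclude chance as the source of the counts. For macroH2A1.1 depletion 1 of 35 divisions reached 18499, with 13295 as the highest other, and for macroH2A1.2 depletion 1 of 35 reached 18599, with 13431. Both of those other divisions joined siDdx5-17 replicate 4 to the second experiment, and they point to the structure of the experiments. Between the isoform depletions the 10 divisions are too few for a share under 0.05. The real division gave 0 calls, a count reached by 10 of 10, and the highest other gave 1.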

How the results depend on the processing

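Leaving out both arrays numbered 4 with siCtrl replicate 3, the blocks over only the arrays compared, and list and overlap tests after quantile normalization were chosen after the data were seen, and the cause of the differences between settings was not tested unless stated. Between siDdx5-17 and siCtrl the 2077 calls became 721 with only the 8 arrays, 4284 with the replicate block, 7281 with array weights, 994 with a 1.5-fold minimum and 969 at the stricter threshold, the last 2 by construction, and 4234 without those 3 arrays. The weights of siCtrl rested mostly on its replicate 1 (9.3, against at most 0.718 for its other arrays). Same-numbered siCtrl and siDdx5-17 arrays had correlations of 0.0847, -0.134, -0.074 and 0.647, and only number 4 correlated best with its own. With siDdx5-17 they were -0.00896, -0.0215 and 0.0351 for macroH2A1.1 and -0.00323, -0.0926 and 0.0847 for macroH2A1.2, only number 3 of the latter best with its own, and the block gave 19220 and 19305 calls. Leaving out 1 array gave 1425 to 2755 calls for siDdx5-17 against siCtrl, 17512 to 18458 for macroH2A1.1, 17670 to 18544 for macroH2A1.2 and 0 between the isoforms. For macroH2A1.1 and macroH2A1.2 against siDdx5-17, quantile normalization gave 11351 and 11027 calls and median centring 11183 and 10825. Both set the array medians equal by construction. Between the isoforms array weights gave 22 calls and the block over 6 arrays 2. The log2 fold of Macroh2a1 in siDdx5-17 + simacroH2A1.1 against siDdx5-17 reversed to -0.27 with quantile normalization and -0.37 with median centring. With an estimated correlation 0 lists shifted in each of the 4 comparisons. For siDdx5-17 against siCtrl 3 lists shifted with the rank test and 3 without the dimmest transcript clusters, in place of 6. The rank test lost G1/S (0.254), microRNA processing (0.0729), TGF-beta (0.11) and p53 (0.0702) and gained ribosomal proteins (0.0447). Without the dimmest clusters G1/S (0.0587), microRNA processing (0.0612) and TGF-beta (0.0623) were lost, with the block microRNA processing (0.0508) and TGF-beta (0.054), where ribosomal proteins were gained (0.0171), and after quantile normalization TGF-beta (0.0991). For macroH2A1.1 depletion 2 shifted with the rank test in place of 4, without splicing factors (0.102) and glycolysis (0.0591), and for macroH2A1.2 splicing factors were lost (0.139). Endothelial markers were lost for both isoforms without the dimmest clusters (0.269 and 0.262) and with only the arrays compared (0.0884 and 0.107). With the block 2 lists lay higher and 0 lower for macroH2A1.1, in place of 1 and 3, and 2 and 0 for macroH2A1.2, in place of 1 and 2. Opposite calls shared with siDdx5-17 against siCtrl fell to 405 and 417 with a 1.5-fold minimum and to medians of 487 and 492.5 with the siDdx5-17 arrays divided, and calls shared between the isoforms to 10027 after quantile normalization. Over the named genes, 5185 values kept direction and side of the threshold, 167 gained a call, 165 lost one and 2 reversed, and over the lists 473 kept both, 12 gained and 43 lost a call.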

Other observations

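The tests of the homologous recombination, autophagy and cohesin lists, of the scale of Ddx5 and Ddx17 and of the 6-array isoform fits and label swaps were chosen after the result was seen. Several genes of homologous recombination were lower in siDdx5-17 than in siCtrl. Of 20 measured, 8 fell and none rose over all genes tested, 9 fell when adjusted over the list alone, 7 after quantile normalization and 3 in the 8-array fit (median -0.30). The recombinase paralogue Rad51c fell 2.30-fold (log2 SE 0.127, adjusted p = 0.00014), the nuclease Mre11a by 1.17 on the log2 scale (SE 0.146, adjusted p = 0.000435), its partner Rad50 by 1.12 (SE 0.13, adjusted p = 0.000267) and Brca1 by 0.63 (adjusted p = 0.00616, 0.0673 with 8 arrays). Camera gave an unadjusted p of 1.78e-06 and 0.213 with an estimated correlation, and the list was chosen after its genes were seen to fall, so these p-values are no independent evidence. Of 21 autophagy genes, 3 rose and 3 fell, or 5 and 4 when adjusted over the list alone, and the list did not shift (unadjusted p = 0.333). Gabarapl1 (1.19, adjusted p = 0.00669), Map1lc3b (0.97, adjusted p = 0.00866) and Sqstm1 (0.30, adjusted p = 0.0125) rose, while Ulk2 (-0.97, adjusted p = 0.000632), Becn1 (-0.91, adjusted p = 0.00234) and Wipi2 (-0.59, adjusted p = 0.00214) fell. With 8 arrays the risers missed the threshold (0.0537, 0.0655 and 0.0556). Of 9 cohesin genes only Smc1a fell, also when adjusted over the list alone (-0.99, adjusted p = 0.00602, 0.0577 with 8 arrays), and the list did not shift (unadjusted p = 0.248).

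As deposited, Ddx5 and Ddx17 in the 6 arrays with a macroH2A1 siRNA lay near siCtrl, at differences of -0.139 and -0.111. Over 2844 transcript clusters called after quantile normalization, the changes in those arrays from siCtrl had positive slopes on the siDdx5-17 changes. The slopes had medians of 0.801 and 0.787 against 0.946 in left-out siDdx5-17 arrays, and the higher median ratio was 0.853. A slope does not give the direction of single clusters, which was not counted. These clusters were chosen with all siCtrl and siDdx5-17 arrays, the left-out ones included, which can raise each slope. No slope for arrays without depletion was computed, so depletion that failed in those arrays is not excluded. After quantile normalization Ddx5 was -0.917 and Ddx17 -0.886 from siCtrl, against -1.42 and -1.119 in siDdx5-17. A difference in scale between the experiments may account for the levels, but these values cannot decide it. The array medians differed by 0.89 between the experiments, so that normalization lowers most genes that lay near siCtrl as deposited. Both tests compare arrays across the experiments and rest on quantile normalization bringing them to 1 scale.

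Between the isoform depletions 3 lists shifted while 0 genes passed. Whether the larger spread of the first experiment hid differences stays open, since a fit of the 6 arrays alone called 0 genes without the replicate block and 2 with it. Unadjusted counts rose from 556 to 1616 without the block and from 1061 to 3481 with it, against 1167 by chance, and the 4 arrangements within numbers are too few for a small p. One array may carry part of the cell-cycle shift, but this is not settled. Without replicate 2 of the macroH2A1.1 group the G2/M list had camera adjusted p = 0.12, while the G1/S list stayed at 0.0333. Replicates 2 and 3 of that group both lay low for G2/M genes, with median deviations of -0.089 and -0.071. Leaving out an array also lowers the power of the test. Among 105 families of like-named genes, 0 passed both fits in siDdx5-17 against siCtrl, where the lowest adjusted p was 0.125, for the Sema family.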
